A study of Mus musculus with 6 samples.

How the data were processed

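Poly(A) RNA from RAW 264.7 cells was sequenced as paired-end Illumina reads after KAPA mRNA HyperPrep library preparation, per the labels' protocols. RNA came from separate plates, 3 of unedited cells (WT) and 3 of cells with an APOBEC1 knockout (KO), per the labels' protocols. The labels do not state how the knockout was made or from how many clones the cells came, so the genotype and any other difference between these lines cannot be told apart, and p-values measure the spread between plates.

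Reads were handled with Trim Galore, FastQC, STAR 2.6.0a, Picard and SAMtools on the mouse build mm10, per the submitters' processing notes. The column names say that the alignments were sorted by coordinate and had duplicates removed, per the file headers. The read counter, its annotation and its use of strand are not given in the sources used here. The authors deposited a table of CPM, read counts scaled to a common library total, for 24848 gene symbols, of which 7683 are listed at 0 in all libraries. No further scaling between libraries is recorded.

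CPM values were whole multiples of what a single read is worth in 100% of values (tolerance 0.01 of a read), so whole reads were recovered: 50493447, 67392191 and 58408190 reads in WT replicates 1, 2 and 3 and 70411383, 59768682 and 66647726 in KO replicates 1, 2 and 3. A read is worth 0.0142 to 0.0198 CPM, and the limit that a count of 0 allows, set at 3 reads, is 0.0426 to 0.0594 CPM. Such floors cover counting error only, since the reads carry no molecular identifiers. The ribosomal RNA precursor Rn45s took 2.75%, 0.381% and 2.43% of reads in the WT libraries and 1.40%, 0.542% and 0.635% in the KO libraries.

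Genes with at least 1 CPM in at least 3 of the 6 libraries were tested, on log2(CPM + 0.5), with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend, no covariates). Genes with a Benjamini-Hochberg adjusted p under 0.05 were called, and those with an absolute log2 fold change of at least 1 were counted as changed at least 2-fold. Apobec1 was also tested with an exact two-sided permutation test. Gene lists written before the data were examined were tested with camera at an inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 29 lists with at least 3 tested members, and beside it with camera at an estimated correlation and with fry. Members of a list were counted by their call over all tested genes, and again with p adjusted over the list alone.

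The genes named in the text follow a rule set before the data were examined. They are Apobec1, then the 12 called genes with the largest positive and the 12 with the largest negative log2 fold change that had at least 5 mean CPM in the higher group and no overlap between groups, then up to 4 called members of each list by adjusted p, or the 2 most abundant if none was called. Cenpa, Gins1, E2f1, B2m and the housekeeping genes listed at 0 were named after their values were seen. Some genes that the rule selects are not reported here.

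Coordinates, transcript lengths, GC content and overlaps come from GENCODE release M21 on the same build (mm10). Of the listed symbols, 24305 matched by symbol, 121 by an older symbol and 422 did not match. Chromosome medians were set against 10000 permutations of genes over chromosomes with Python 3.11.15 and scipy 1.17.1.

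The libraries were checked before groups were compared. Pearson correlations across genes of log2(CPM + 0.5) were 0.988 to 0.996 within WT, 0.996 to 0.998 within KO and 0.969 to 0.978 between groups. Genes are not independent replicates, so these describe the libraries. Recovered reads of any pair of libraries differed by far more than sampling noise (chi-square per degree of freedom of at least 41.9), so no library was taken for a copy of another. The first principal component held 76.6% of the variance and separated the groups.

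The fit was tested on simulated counts drawn from these libraries' means and sizes for the comparison of KO with WT, with 200 genes changed. Among 10571 tested genes it recovered 79.1% of those changed 1.5-fold, 98.5% of those changed 2-fold and 100% of those changed 4-fold, with 23 false calls. The simulated genes varied independently of each other and far fewer changed than were called in the data. The simulation therefore does not give the share of false calls in the real comparison.

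Alternatives set before the data were examined were other pseudocounts, CPM minimums, scalings and limma settings, a replicate block, edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads, and leaving out each library. Chosen after the data were seen were the removal of a trend with length and GC content from each library (which also centred each library), rescaling without Rn45s, and runs without genes that overlap another gene and without the genes of chromosome 2. The edgeR quasi-likelihood test called 3359 genes and DESeq2 3758. RNA editing was not analysed here.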

Results

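RNA sequencing was used to compare RAW 264.7 cells, a macrophage-like line that arose from a tumour induced by Abelson murine leukaemia virus in a BALB/c mouse, with RAW 264.7 cells in which Apobec1 had been knocked out. APOBEC1 is a cytidine deaminase that converts C to U in RNA, most often in 3' untranslated regions in macrophages. The series was made to test a method that measures RNA editing from sequencing traces against RNA sequencing. The table used here holds the level of each gene and no editing calls, so the comparison it allows is that of gene levels between the genotypes. There were 3 wild-type (WT) and 3 knockout (KO) libraries, each from RNA of a separate plate. The libraries held 50493447 to 70411383 reads assigned to genes. Levels are given as read counts scaled to the library total (CPM) ± SD over the 3 libraries of a group, log2 fold changes (KO against WT, on log2(CPM + 0.5)) as estimate ± SE, and adjusted p as limma with Benjamini-Hochberg adjustment gave it. A fold change on that scale understates the change of genes at low levels. Folds are ratios of mean CPM.

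Apobec1 mRNA was present in all 6 libraries at 18809 to 29035 reads. Apobec1 (ENSMUSG00000040613.14, mm10 chromosome 6, 122577792 to 122602444, minus strand, protein-coding) stood at 399.8 ± 29.3 CPM in WT and 347 ± 12.5 CPM in KO (n = 3 each), 13.3% lower in KO. The KO values, 339 to 361 CPM, lay below all WT values, 373 to 431 CPM. The log2 fold change was -0.20 ± 0.07 and missed the threshold (adjusted p = 0.0663), and the exact two-sided permutation test gave p = 0.1, the smallest that 3 against 3 libraries allow. The median log2 fold change of all 520 tested genes on chromosome 6 was -0.16, and 43.3% of them were as low as Apobec1 or lower. The level of Apobec1 thus does not stand apart from its chromosome. The labels do not say which change was made in the gene. A transcript can persist after a small edit, so this level does not check the labels. The difference passed the threshold without WT replicate 1 (log2 fold change -0.25, adjusted p = 0.0169) and under 5 other settings.

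The genotypes differed in 3230 of 10614 tested genes, 1436 higher and 1794 lower in KO. Of these, 392 changed at least 2-fold, 120 higher and 272 lower, and for 391 of the 392 the values of the groups did not overlap. Over all tested genes, 46.4% had groups without overlap, against 10% by chance. Among the genes that rose most were Nedd4l, a ubiquitin ligase (0.370 ± 0.0695 to 14.0 ± 0.595 CPM, log2 fold change 4.06 ± 0.10), and Alox5, the enzyme that starts leukotriene synthesis (1.86 ± 0.277 to 34.7 ± 1.56 CPM, 18.6-fold). Il1rn, the interleukin-1 receptor antagonist, rose from 7.999 ± 0.612 to 90.3 ± 8.08 CPM (11.3-fold), and Car2, carbonic anhydrase 2, from 46.2 ± 3.00 to 236 ± 2.70 CPM (5.10-fold). The carbonyl reductase Cbr3 rose 19.5-fold, Ranbp3l 5.66-fold, Slc28a2, a nucleoside transporter, 6.26-fold and Fam212b 17.4-fold.

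Among the genes that fell most was Clec7a, which encodes the beta-glucan receptor Dectin-1 and fell from 18.8 ± 3.54 to 0.0601 ± 0.0284 CPM, with 2 to 6 reads in each KO library (log2 fold change -5.09 ± 0.14). Atp2a3, a calcium pump of the endoplasmic reticulum, fell from 14.9 ± 0.821 to 0.148 ± 0.0508 CPM. Nedd9, an adhesion scaffold, fell from 10.3 ± 1.23 to 0.0292 ± 0.0371 CPM, and Svil, the actin-binding supervillin, from 12.5 ± 0.731 to 0.215 ± 0.101 CPM. Cd24a fell 17.2-fold, from 68.3 ± 8.13 to 3.98 ± 0.256 CPM. Igf2r, the cation-independent mannose 6-phosphate receptor, fell 12.4-fold, from 145.7 ± 3.00 to 11.8 ± 1.04 CPM. The antisense gene Airn shares 32.5% of its span. Reads of the shared part cannot be assigned to either gene because the counting is not stated to use strand. The same holds for 7.73% of the span of Hectd2os, antisense to Hectd2, which fell from 10.9 ± 3.29 to 0.393 ± 0.0974 CPM. Cul9, Adcy6 and Slc43a3 fell with log2 fold changes of -3.80, -3.66 and -3.54.

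**Figure D1:**
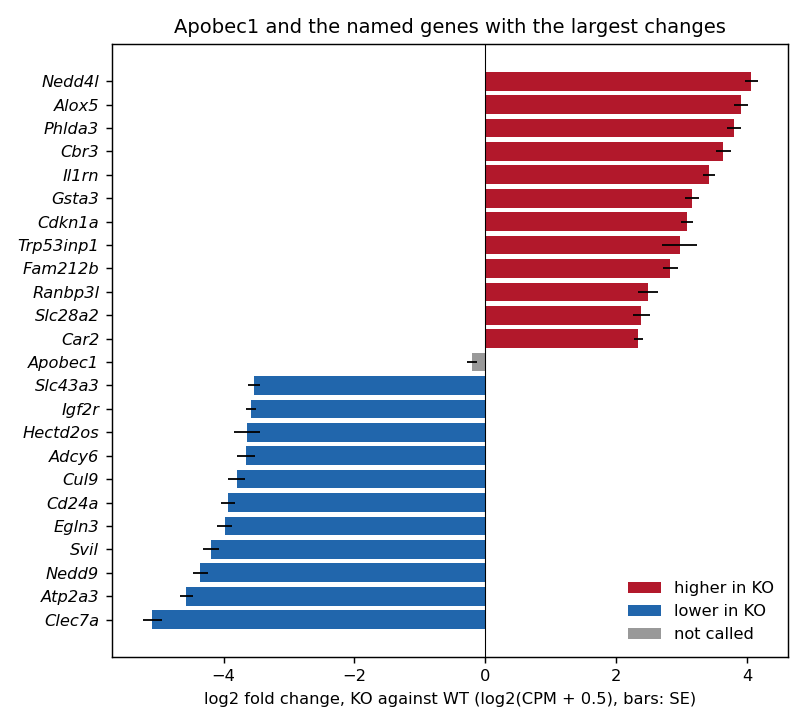
Log2 fold change of KO against WT on log2(CPM + 0.5), with SE as error bars, for Apobec1 and for the genes with the largest changes that the text names. Apobec1, in grey at -0.20, was not called, while the others run from -5.09 for Clec7a to 4.06 for Nedd4l.

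Limma made these calls, and each p measures the spread between plates of these lines. The number of changed genes was 1973 without KO replicate 1. After a trend with transcript length and GC content was removed from each library it was 5076, with 2942 higher and 2134 lower. Quantile normalization gave 1570 higher and 1486 lower (166 and 182 changed at least 2-fold), so that the larger direction over all called genes changed under both settings. The trend fit also centred each library, and the median log2 fold change of tested genes went from -0.02 to 0.03. The turned direction there cannot be assigned to the trend alone.

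Genes of chromosome 2 were higher in KO along the whole chromosome. Of the 863 tested genes there, 503 rose, 45 fell and 315 were not called, and 84.4% had a positive log2 fold change, against 43.0% elsewhere. Chromosome 2 thus held 8.17% of the tested genes and 35.1% of the genes that rose. Its median log2 fold change lay 0.36 above that of all tested genes (adjusted p = 0.000667, from 10000 permutations of genes over chromosomes, a p that is the smallest they can give before adjustment). Per library, the median difference from the WT mean was 0.36 to 0.37 in the KO libraries and -0.003 to 0.005 in the WT libraries. The shift equals a ratio of 1.28. Il1rn, at chromosome 2, 24336853 to 24351494, is among these genes, but its 11.3-fold rise is far larger than the shift. Of the called genes there, 18 were at least 2-fold higher and 16 at least 2-fold lower. Slc28a2 (6.26-fold higher) and Slc43a3 (log2 fold change -3.54) also lie on chromosome 2. Without the genes of chromosome 2, 2552 genes were called, 876 higher and 1676 lower. On chromosome 6 the shift went down, by a median of -0.14 relative to all tested genes (adjusted p = 0.000667), with 155 of 520 genes lower and 30 higher. Smaller downward shifts also passed on chromosome 17 (-0.05, adjusted p = 0.001), chromosome 7 (-0.04, adjusted p = 0.000667) and chromosome 3 (-0.04, adjusted p = 0.0156). This p permutes genes and leaves out the spread between libraries: on chromosomes 7 and 3 the library medians of the groups overlapped, while on chromosomes 2, 6 and 17 they did not.

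**Figure D2:**
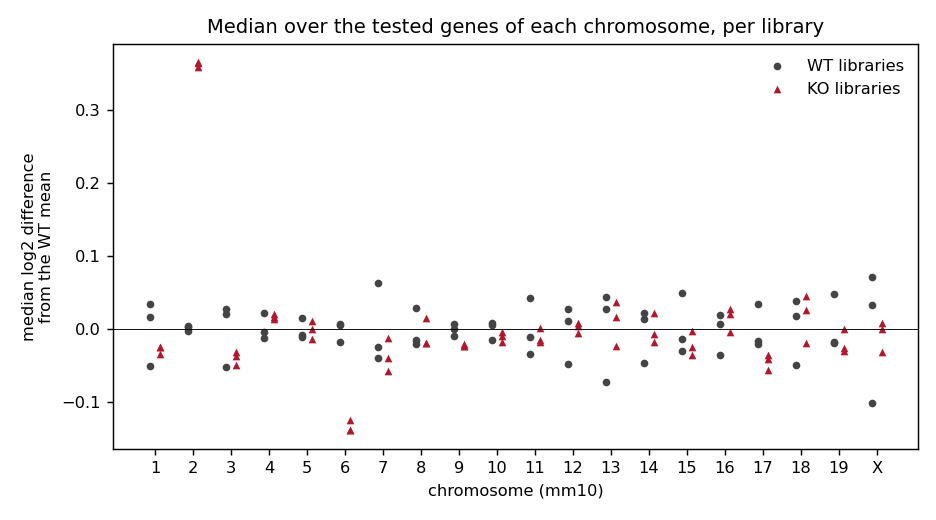
Median over the tested genes of each chromosome (x axis) of the log2 difference from the WT mean (y axis), centred on the median of all tested genes, with a point per library. The 3 KO libraries stand at 0.36 to 0.37 on chromosome 2 and at -0.14 to -0.12 on chromosome 6.

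Gene lists fixed before the data were examined were tested with camera at a preset inter-gene correlation of 0.01. Of 29 lists with at least 3 tested members, 12 were called, 7 up and 5 down. With an estimated correlation 0 were called, 3 of them having an unadjusted p under 0.05. The preset test called 6 to 13 lists in each of the other 9 splits of the libraries, in which limma and edgeR called 0 genes and 3 to 706 had an unadjusted p under 0.05 in limma. Member counts are therefore given with each list, and for each list that camera or fry called also the p of the fry test. Of all 10614 tested genes 30.4% were called, 1436 higher and 1794 lower, and a count near these shares does not set a list apart. Counts can also move together where members vary together, as for ribosomal protein genes (estimated correlation 0.83). Fry does not set a list against the other genes. Fry called 13 lists in the real split and 0 in the others (at most 3 at an unadjusted p under 0.05). The other splits mix the genotypes, so the genotype difference widens the spread within their groups and lowers such calls. The 0 calls there therefore do not check the fry test.

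Targets of the tumour suppressor p53 rose together: 15 of 22 tested members were higher and 2 lower, and as many when adjusted over the list alone, with a median log2 fold change of 0.53 (camera adjusted p = 1.43e-06, adjusted p = 0.311 with an estimated correlation, fry adjusted p = 0.000383). Cdkn1a, the cyclin-dependent kinase inhibitor p21, rose 8.76-fold, from 11.8 ± 1.18 to 103 ± 8.68 CPM. Phlda3, an inhibitor of Akt, rose 20.2-fold, from 1.03 ± 0.0771 to 20.9 ± 2.28 CPM, and Trp53inp1 8.46-fold. Zmat3 rose from 23.9 ± 1.64 to 59.7 ± 3.40 CPM and the death receptor Fas from 0.444 ± 0.106 to 2.38 ± 0.195 CPM. Of the 22 members, 0 lie on chromosome 2.

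Genes of the cell cycle were also higher. In the list of DNA replication and S phase, 16 of 31 members rose and 0 fell (19 and 0 adjusted over the list alone; median 0.24, camera adjusted p = 1.28e-07, adjusted p = 0.311 with an estimated correlation, fry adjusted p = 0.000930). Rrm2, a subunit of ribonucleotide reductase, rose 1.66-fold to 214 ± 7.28 CPM, and Ccne1, cyclin E1, 1.47-fold. No member, 0 in limma, edgeR and DESeq2, was lower at an unadjusted p under 0.05. In the list of mitosis and G2/M, 15 of 32 members rose and 1, Cenpa, fell (19 and 1 adjusted over the list alone; median 0.26, camera adjusted p = 5.72e-07, adjusted p = 0.311 with an estimated correlation, fry adjusted p = 0.00551). The strongest mitotic members, Tpx2 (1.59-fold), Aurka (1.64-fold), Bub1b (1.46-fold) and Ube2c (1.69-fold), lie on chromosome 2, as do 6 of the 15 that rose, and the S phase members Pcna, Gins1 and E2f1. Without the genes of chromosome 2 the median of the mitotic list was 0.21 (camera adjusted p = 1.12e-05, adjusted p = 0.359 with an estimated correlation, fry adjusted p = 0.0307).

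The ATF4 response to amino acid shortage and the NRF2 response to oxidants were both higher. Of 25 ATF4 genes, 15 rose and 1 fell (17 and 1 adjusted over the list alone; median 0.26, camera adjusted p = 1.03e-05, adjusted p = 0.416 with an estimated correlation, fry adjusted p = 0.0103). Sesn2, also induced by p53, rose from 14.7 ± 2.54 to 35.5 ± 3.80 CPM, Trib3 from 13.1 ± 1.94 to 27.8 ± 1.46 CPM, Chac1 from 6.61 ± 0.402 to 13.2 ± 1.26 CPM and Mthfd2 1.35-fold. Trib3 and Chac1 lie on chromosome 2. Of 22 NRF2 genes, 13 rose and 2 fell (15 and 2 adjusted over the list alone; median 0.35, camera adjusted p = 3.72e-05, adjusted p = 0.311 with an estimated correlation, fry adjusted p = 0.000971). The glutathione transferase Gsta3 rose 10.8-fold, and Gclm, a subunit of the enzyme that limits glutathione synthesis, from 64.4 ± 0.521 to 124 ± 0.911 CPM. Cat, catalase, on chromosome 2, rose 2.24-fold, while Me1, malic enzyme, fell 3.82-fold from 218 ± 10.2 to 57.1 ± 1.35 CPM.

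Cytosolic ribosomal protein genes fell as a group. Of 47 members, 33 were lower and 0 higher (40 and 0 adjusted over the list alone), with a median of -0.33 (camera adjusted p = 1.67e-08, adjusted p = 0.680 with an estimated correlation, fry adjusted p = 0.0452). Rplp0 went from 2084 ± 143 to 1386 ± 149 CPM, Rpl32 from 2093 ± 175 to 1408 ± 153 CPM, Rpl10a from 849 ± 47.9 to 635 ± 39.0 CPM and Rpl22 from 537 ± 13.4 to 424 ± 15.6 CPM. The direction held under each scaling tried. With the length and GC trend removed and each library centred, the median was -0.25 and the fry call was lost (fry adjusted p = 0.0532). Camera at the preset correlation kept its call there (camera adjusted p = 8.68e-07, adjusted p = 0.801 with an estimated correlation). EdgeR called 20 members lower and DESeq2 32, and 0 were higher at an unadjusted p under 0.05 in either or in limma. Genes of this family share reads with many processed pseudogenes, and the authors' treatment of such reads is not given in the sources used here.

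The lists of cholesterol synthesis and of LXR targets were called down. Of 24 genes of cholesterol synthesis, 17 fell and 1 rose (18 and 1 adjusted over the list alone; median -0.38, camera adjusted p = 5.15e-06, adjusted p = 0.311 with an estimated correlation, fry adjusted p = 0.000930). Insig1, a sterol sensor of the endoplasmic reticulum, fell from 179 ± 6.81 to 102 ± 1.83 CPM, Nsdhl from 91.9 ± 1.19 to 60.7 ± 2.42 CPM and Acat2 from 82.1 ± 1.73 to 56.7 ± 1.60 CPM. Of 12 targets of the sterol receptor LXR, 8 fell and 1 rose (9 and 2 adjusted over the list alone; median -0.33, camera adjusted p = 0.0287, adjusted p = 0.400 with an estimated correlation, fry adjusted p = 0.00139). Scd1, a stearoyl-CoA desaturase, fell 7.25-fold, from 23.9 ± 0.426 to 3.29 ± 0.224 CPM. The camera call of the LXR list was lost without WT replicate 1, without a filter on low values and without genes that overlap another gene.

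The lists of alternative macrophage activation and of hypoxia and glycolysis were called down, each with members on both sides. Of 9 alternative activation genes, 6 fell and 1 rose (7 and 1 adjusted over the list alone; median -1.95, camera adjusted p = 0.000284, adjusted p = 0.311 with an estimated correlation, fry adjusted p = 0.000282). Besides Clec7a these were led by the lectin genes Clec10a (9.49 ± 0.0962 to 1.12 ± 0.0938 CPM) and Mgl2 (2.10 ± 0.199 to 0.0424 ± 0.0364 CPM) and by Pdcd1lg2, which encodes PD-L2 (2.35 ± 0.207 to 0.186 ± 0.0566 CPM). At a minimum of 5 CPM, which removes several of these genes, the camera call was lost. Of 28 hypoxia and glycolysis genes, 12 fell and 4 rose (13 and 4 adjusted over the list alone; median -0.12, camera adjusted p = 0.0129, adjusted p = 0.400 with an estimated correlation, fry adjusted p = 0.000930). Egln3, a prolyl hydroxylase that marks HIF for degradation, fell from 15.6 ± 0.505 to 0.522 ± 0.140 CPM, Ndrg1 2.75-fold and Bnip3 2.72-fold. P4ha2, a collagen prolyl hydroxylase, had 65 to 84 reads in each WT library (1.23 ± 0.0721 CPM) and 0 in each KO library, at least 24.4-fold lower against a floor of 3 reads per library.

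Genes of cytoskeleton and adhesion were called up with members on both sides, 10 of 28 higher and 4 lower, and as many adjusted over the list alone (median 0.10, camera adjusted p = 0.0279, adjusted p = 0.400 with an estimated correlation, fry adjusted p = 0.00257). The integrin gene Itgax, which encodes CD11c, rose 4.43-fold to 30.9 ± 2.79 CPM, Cd44 2.63-fold to 431 ± 8.65 CPM, Vim 1.90-fold to 1138 ± 73.9 CPM and Flna 1.65-fold. Cd44 and Vim lie on chromosome 2. The camera call of this list was lost without WT replicate 2 and under quantile normalization. Of 34 lysosomal genes 12 rose and 4 fell, and as many adjusted over the list alone (median 0.08, camera adjusted p = 0.0390, adjusted p = 0.784 with an estimated correlation, fry adjusted p = 0.0895). Ctsl and Ctsz, which encode cathepsins, rose 1.43-fold and 1.52-fold, and Ctsh, another cathepsin gene, fell 4.48-fold. The lysosomal call was lost under 12 of 24 alternative settings, among them the runs without WT replicate 2 and without KO replicate 2.

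**Figure D3:**
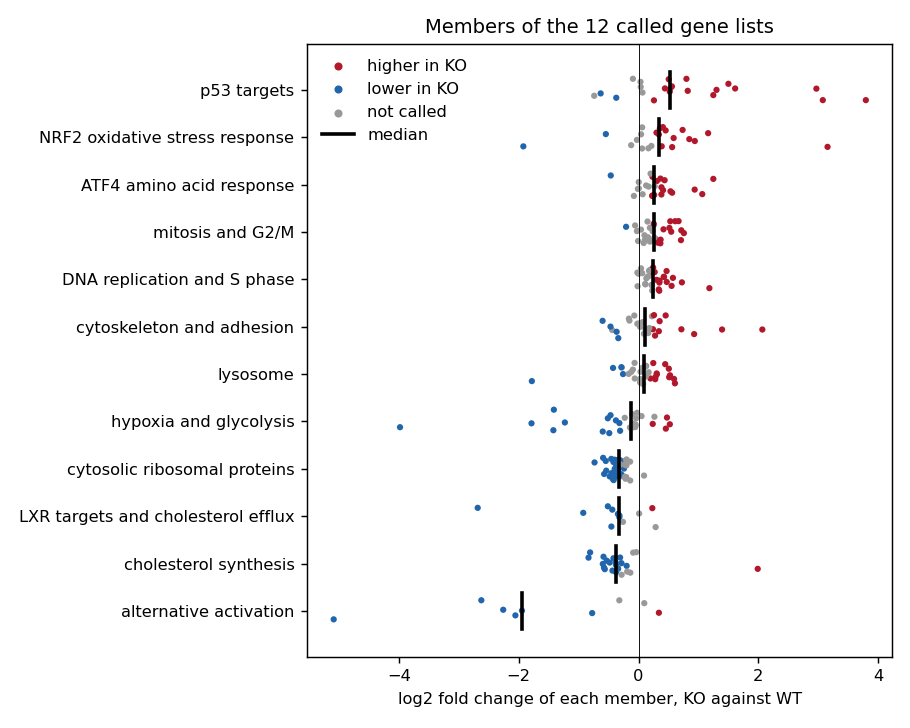
Log2 fold change of each tested member (points, x axis) of the 12 called lists (rows), coloured by the call of the gene, with a black line at the median. Medians run from -1.95 for alternative activation to 0.53 for p53 targets.

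Lists tied to Apobec1 itself were not called by camera or fry in the main run. With the length and GC trend removed, fry called 2 of them up. These were the edited transcripts (fry adjusted p = 0.0313, camera adjusted p = 0.322) and the cofactors (fry adjusted p = 0.0119, camera adjusted p = 0.141). Of 20 tested transcripts known from earlier work as APOBEC1 editing targets, 4 rose and 3 fell (6 and 4 adjusted over the list alone; median 0.12, camera adjusted p = 0.165). Rnf128 rose from 19.5 ± 4.65 to 60.2 ± 6.13 CPM, App, the amyloid precursor protein gene, from 124 ± 1.91 to 166 ± 6.33 CPM, and Cd36, a scavenger receptor, from 18.1 ± 3.19 to 33.4 ± 0.647 CPM, while Mtmr2 fell from 239 ± 17.7 to 182 ± 4.85 CPM. B2m, a further target, is listed at 0 in every library. Among 8 cofactors and binding partners only Dnajb11 rose in the main test, from 182 ± 1.94 to 209 ± 5.89 CPM, a call lost under 7 of 21 alternatives, among them the runs without WT replicates 2 and 3 and without each KO replicate (median 0.12, camera adjusted p = 0.203, 0 higher adjusted over the list alone, 2 at an unadjusted p under 0.05). Of 10 tested neighbours of Apobec1 on chromosome 6, Clec4d (172 ± 6.50 to 371 ± 14.6 CPM) and Clec4n (6.28 ± 0.600 to 11.6 ± 0.544 CPM) rose and Foxj2 (61.7 ± 2.37 to 43.5 ± 2.18 CPM) fell (camera adjusted p = 0.720; 2 and 2 adjusted over the list alone). Apobec3 stood at 25.8 ± 1.64 CPM in WT and 30.3 ± 1.25 CPM in KO (adjusted p = 0.0543), a difference called under 7 of 21 alternatives, edgeR, DESeq2, quantile and median-of-ratios scaling and the run without WT replicate 2 among them. Adjusted over the 2 tested genes of the APOBEC family alone, Apobec3 passed as higher and Apobec1 as lower. Adar stood at 80.7 ± 4.94 and 76.6 ± 5.82 CPM (adjusted p = 0.510). Of the 3 tested adenosine deaminase genes limma, edgeR and DESeq2 called 0, as did limma adjusted over the list alone (camera adjusted p = 0.464), and 1 was lower at an unadjusted p under 0.05 in limma.

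Apart from alternative activation, described above, the macrophage and immune lists held changes in both directions and were not called by camera in the main run. Fry called the interferon-stimulated list down and the inflammatory list up there. Macrophage identity gained a call under 2 of 24 alternatives, and fry called it up with the length and GC trend removed (fry adjusted p = 0.0127). Fry called MHC class I presentation down without the genes of chromosome 2 (fry adjusted p = 0.0394). Of 24 interferon-stimulated genes, 8 fell and 4 rose, and as many adjusted over the list alone (median -0.12, camera adjusted p = 0.481, fry adjusted p = 0.0274). Without the genes of chromosome 2, among them the member Ifih1, the fry call was lost (fry adjusted p = 0.0849). With the length and GC trend removed it was kept (fry adjusted p = 0.00120). Usp18 fell from 15.6 ± 0.418 to 6.85 ± 0.636 CPM, Oas3 from 30.5 ± 0.872 to 16.3 ± 0.682 CPM, Ifi44 from 3.53 ± 0.895 to 0.525 ± 0.0491 CPM and Ifih1, on chromosome 2, from 2.24 ± 0.215 to 0.570 ± 0.0153 CPM. Of 30 macrophage identity genes, 10 rose and 4 fell (11 and 7 adjusted over the list alone; median 0.03, camera adjusted p = 0.165). The fractalkine receptor gene Cx3cr1 rose 3.15-fold, the complement gene C1qc from 0.672 ± 0.102 to 4.23 ± 0.948 CPM and the lysozyme gene Lyz2 1.75-fold, while the transcription factor gene Irf8 fell from 54.0 ± 2.79 to 34.4 ± 2.01 CPM. Of 17 genes of MHC class I presentation, 8 fell and 3 rose (8 and 4 adjusted over the list alone; median -0.10, camera adjusted p = 0.359), among them Nlrc5, H2-M3 and Psmb9, which fell, and Pdia3, on chromosome 2, which rose 1.56-fold. Of 19 inflammatory genes, 4 rose and 5 fell (6 and 5 adjusted over the list alone); their median was -0.07, their mean 0.09 and the camera direction up (camera adjusted p = 0.732), and fry called the list up (fry adjusted p = 0.0103). Without Il1rn, its tested member on chromosome 2, the mean was -0.09 and the fry call was lost with its direction turned (fry adjusted p = 0.788). Ccl2 rose from 3.93 ± 0.349 to 8.67 ± 0.499 CPM and Nfkbiz fell 3.15-fold from 25.2 ± 4.51 CPM.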

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

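The runs with the length and GC trend removed, without Rn45s, without overlapping genes and without the genes of chromosome 2 were chosen after the data were seen. No named gene changed direction while called under any limma, edgeR or DESeq2 setting run, nor did a list in camera, but the larger direction of the called genes turned under quantile normalization and with the length and GC trend removed. The lower Apobec1 level passed the threshold under quantile normalization (log2 fold change -0.27, adjusted p = 0.0132), sample weights (-0.21, 0.0021), DESeq2 (-0.18, 0.0327), removal of the length and GC trend (-0.16, 0.0249) and rescaling without Rn45s (-0.22, 0.0409). Over the runs that leave out a library its log2 fold change was -0.25 to -0.15. The count of 3230 changed genes became 5743 with sample weights and 5076 with the length and GC trend removed, and ranged from 1973 (without KO replicate 1) to 3761 (without WT replicate 1) over the runs that leave out a library. With the replicate block it was 2009. The labels do not say that the numbers pair plates. Same-numbered libraries deviated from their group means with correlations of -0.25, -0.64 and -0.17, and pairs with different numbers ran from -0.44 to 0.61. Centring within groups of 3 constrains these values, so they cannot settle whether plates were paired. No sample correlated best with its own number. The count of 392 genes changed at least 2-fold was 211 at a minimum of 5 CPM, where fewer genes were tested. Of the 12 called lists, 0 were called with an estimated correlation. The cause of the other shifts was not tested. Of the comparisons of named genes with an alternative, 2702 kept their side of the threshold, 46 lost a call and 7 gained one. For lists these numbers were 658, 29 and 7. Depth limits genes in which a group holds a few reads per library, such as Clec7a and Nedd9 in KO.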

Other observations

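The tests of the effect of the genes of chromosome 2, of runs of neighbouring genes and of overlap over all protein-coding genes were chosen after the patterns they bear on were seen. Lists not described above were not called by camera at a preset correlation in the main run. Oxidative phosphorylation gained a call under 3 of 24 alternatives. With the length and GC trend removed, fry called 4 of these lists up. They were Toll-like receptors (fry adjusted p = 0.0127), MYC targets (0.0183), the unfolded protein response (0.0256) and immediate early genes (0.0477). Of 9 osteoclast genes 3 rose and 3 fell, and as many adjusted over the list alone (median 0.04, mean -0.16, camera direction up and fry direction down, camera adjusted p = 0.732). Ctsk, the collagen-degrading cathepsin K, fell 6.64-fold, from 365 ± 4.62 to 55.0 ± 2.81 CPM, and Itgb3 fell from 6.09 ± 0.718 to 0.550 ± 0.155 CPM, while Car2 and Atp6v0d2 (3.28 ± 0.618 to 8.16 ± 0.599 CPM) rose. Of 5 MHC class II genes, Ctss, cathepsin S, rose from 946 ± 75.7 to 1689 ± 70.5 CPM and Cd74, the invariant chain, fell from 110.1 ± 12.3 to 52.9 ± 4.03 CPM (median -0.03, camera direction up, adjusted p = 0.852, 1 and 1 adjusted over the list alone). Of 25 Toll-like receptor genes 6 rose and 3 fell, and as many adjusted over the list alone (camera adjusted p = 0.359), with Tlr8 from 0.895 ± 0.265 to 5.39 ± 0.532 CPM. Of 17 genes of fatty acid oxidation and PPAR targets 3 rose and 5 fell, and as many adjusted over the list alone (camera adjusted p = 0.732), with Cpt1a, the carnitine palmitoyltransferase, rising from 33.7 ± 0.0829 to 54.2 ± 3.36 CPM, and Angptl4 (7.49 ± 0.925 to 3.87 ± 0.313 CPM) and Fabp4 (11.8 ± 0.218 to 7.48 ± 0.720 CPM) falling.

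Of 22 genes of the unfolded protein response 5 rose and 2 fell, and as many adjusted over the list alone (camera adjusted p = 0.165): Hspa5, the chaperone BiP, on chromosome 2, rose 1.44-fold, and Ern1 and Xbp1 fell. Of 38 nuclear genes of oxidative phosphorylation 4 rose and 0 fell (2 and 0 adjusted over the list alone; camera adjusted p = 0.174), of which Atp5c1 and Ndufs3 lie on chromosome 2; 0 fell at an unadjusted p under 0.05 in limma, edgeR or DESeq2. Of 23 MYC targets 2 rose and 1, Ldha, fell (1 and 1 adjusted over the list alone; camera adjusted p = 0.272). Of 18 immediate early genes 4 rose and 4 fell, and as many adjusted over the list alone (median -0.04, camera direction up, adjusted p = 0.741), and of 6 replication-dependent histone genes 1, Hist1h2bc, rose (1 adjusted over the list alone; median -0.23, camera adjusted p = 0.741). Of the mitochondrially encoded genes 0 are in the table. Markers of other cells were too few at 1 CPM for a list test. Blnk, a B cell marker, was at 66.8 ± 1.07 CPM in WT and 45.1 ± 1.21 in KO, the T cell marker Lck at 3.99 ± 0.597 and 6.71 ± 0.441, the dendritic markers Itgax at 6.96 ± 0.270 and 30.9 ± 2.79 and Zbtb46 at 4.34 ± 0.426 and 1.62 ± 0.184, the neutrophil markers S100a8 at 0.944 ± 0.112 and 3.99 ± 0.761 and Csf3r at 2.08 ± 0.312 and 0.655 ± 0.0989, the platelet marker Pf4 at 15.0 ± 0.791 and 9.14 ± 0.738, and the endothelial marker Vwf at 39.6 ± 0.514 and 24.7 ± 3.37. The most abundant fibroblast marker, Acta2, stood at 0.458 ± 0.0495 and 0.826 ± 0.238.

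The 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.05. The real split called 3230 genes, 392 of them changed at least 2-fold, and the other splits called at most 0 with limma or edgeR (at most 706 at an unadjusted p under 0.05 in limma), so 1 of the 10 splits gave as many in either count. For lists the real split gave 12 and the highest other 13, so 3 of the 10 splits gave as many. The preset list test therefore calls about as many lists in splits that mix the genotypes. In these splits the genotype difference adds to the spread within each group. Low counts from limma, edgeR and fry there follow from the design and do not test the calls of the real split.

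The higher levels along chromosome 2 were weighed against copy number and a trend with length and GC content. A prediction set before the medians were computed asked for a chromosome more than 0.25 from all tested genes. Chromosome 2 stood 0.36 away (permutation adjusted p = 0.000667). All 42 runs of 40 neighbouring tested genes on it lay above 0.18, the highest that 95% of 200 permuted orders reached. The highest run elsewhere was at 0.13, and 4 runs, on chromosomes 1, 17, 7 and 6, lay below the lower bound of -0.21, down to -0.25. Chromosome 6, at -0.14, stayed within 0.25, but each run on it was negative, from -0.22 to -0.08. Copy number was not weighed for chromosome 6. Removing the length and GC trend kept 102% of the distance, which argues against that trend as the whole cause. A candidate explanation is a larger share of chromosome 2 copies in the KO line: the shift equals a ratio of 1.28, and no DNA was measured here, so a gain in KO, a loss in WT and regulation along the chromosome stay open, as does any link to the knockout.

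The rise of p53 targets was weighed in the same way. After the length and GC trend was removed, the list's median was 0.62, 118% of its value before. That fit also centred each library, so the 118% does not stem from the trend alone. The list stayed past the threshold with fry (adjusted p = 1.63e-05) and with camera at the preset correlation (adjusted p = 1.87e-05, adjusted p = 0.205 with an estimated correlation), which argues against that trend as the whole cause. Without the genes of chromosome 2 the median was 0.53 (camera adjusted p = 3.67e-08, adjusted p = 0.290 with an estimated correlation, fry adjusted p = 0.000384), as 0 of its 22 tested members lie there. The loss of Apobec1 and another difference between the lines cannot be told apart, since the labels name 2 cell populations, WT and KO, and no clones, and the shift of chromosome 2 shows that more than Apobec1 may differ between them. Other knockout clones and unedited clones carried alongside would separate these explanations.

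Several genes that most cells use are listed at or near 0 in every library, among them B2m, Rpl34, Rps15, Rps27 and Ndufs7. If reads were dropped where another gene lies over a gene, low genes should lie inside other genes more often. Among 402 genes chosen by housekeeping name prefixes, 35 stayed under 0.5 CPM in all libraries, and 22.9% of these had at least 90% of their span inside another listed gene, against 1.91% of the other 367 (Fisher's exact one-sided p = 6.17e-06). Restricted to protein-coding genes, a restriction added after the prediction, it was 3 of 28 against 7 of 365 (Fisher's exact one-sided p = 0.0278), since 5 of the 8 overlapped genes are pseudogenes. Over all protein-coding genes, 68.3% of 782 with such an overlap are listed at 0, against 22.6% of the others. Among those with no overlap at all it is 26.8%, so smaller overlaps do not go with more genes at 0. Dropped reads may account for overlapped genes such as B2m inside Patl2. However, 27 of the 35, such as Rpl34, Rps15, Rps27 and Ndufs7, lack such an overlap. Some of the 35 are tissue-restricted family members, and no biological explanation was tested.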
